A study of Mus musculus with 6 samples.

How the data were processed

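Total RNA of whole liver from 6 TAA-treated mice was measured by RNA sequencing. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra RNA kit for Illumina, whose name in the labels does not mention strand marking. The authors deposited raw counts per gene for all 6 mice in a single table of 21983 gene symbols. Trimmomatic, FastQC, STAR and HTSeq, and the genome build mm10, are named per the submitters' processing notes, without versions. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping antisense genes cannot be told apart, and how reads of near-identical genes were treated is not known. The table held whole numbers, 0 repeated symbols, 0 summary rows and 0 columns of other samples, and 5067 genes had no count in any mouse.

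Mice were assigned to genotypes from the sample titles, and columns to mice by the mouse number. The numbers are not shared between genotypes, so no pairing was used. The labels describe the samples as separate mice. Total counts ranged from 13303884 to 16462278; TMM factors ranged from 0.909 to 1.20. The 20 most abundant genes took between 18.3% and 22.7% of the counts of a mouse. Intervals from counts cover counting error only.

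Counts were filtered with filterByExpr, which kept 13153 genes, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on all 6 mice with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 of knockout over control, with the standard error taken from the fold change and the F statistic; the biological coefficient of variation was 0.268. CPM values are counts divided by the TMM-scaled library size. The interval of Prmt1 is at the 95% level from the t distribution with the 8.75 residual degrees of freedom of the fit. The two-sided exact permutation test of Prmt1 used log2 CPM and the 20 assignments of mice.

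Before the data were examined, 36 gene lists of liver cell types, fibrosis and metabolism were written from general knowledge (836 symbols, of which 734 were tested). Each of the 35 lists with at least 5 tested members was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and the directional test of fry were run beside it. The number of members past adjusted p 0.05 was counted over all genes tested and adjusted over the list alone. Some genes are members of more than one list. List means per mouse are means of log2 CPM.

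Genes were named by a rule of 3 parts, fixed at the same time. The first takes Prmt1 and 10 fibrosis genes whatever their p. The second takes the 10 genes with the smallest p that had at least 1 CPM in the higher group and groups that do not overlap, because fewer than 5 genes passed. The last takes the 2 members with the smallest p of each list. Genes with placeholder names were left out of the second part, and some genes that the rule takes are not reported here. Col18a1, Il1r1, Rgs5, Ccl2, Il1rn, Cxcr2, S100a8, Il1r2, Oat, Znrf3, Cyp8b1 and Akr1b8, and in the closing section Id3 and other BMP target genes, were chosen after their values were seen. The BMP ligand genes of the closing section were not taken by the rule either. Gene positions come from GENCODE release M21 on GRCm38, the same assembly as mm10; 21896 of 21983 symbols matched it once.

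The alternatives were RLE size factors, total counts only, no low-count filter, at least 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, a robust edgeR fit, the 20 most abundant genes left out, an adjusted p of 0.10 and each mouse left out in turn. The newer fit of edgeR, limma-voom with a weight per library, a term for mouse number (42 and 49 against those over 80) and the 4 mice numbered over 80 alone were added after seeing the data. The test was checked on counts simulated from the same genes, means and library sizes in 5 runs, with 100 genes changed 2-fold and 100 changed 4-fold in each. It made 118.6 calls per run on average, 9.6 of them false, and found the shifted list in 5 of 5 runs with 1 of 162 tests of other lists called. Genes were simulated independently of each other, so this check does not measure false list calls in real libraries, where genes are correlated. Other splits of the mice gave 14 to 25 lists, though such splits still hold part of any genotype difference.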

Results

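RNA from whole liver was sequenced in 6 C57BL/6 mice that had received thioacetamide (TAA), a hepatotoxin whose long-term use scars the liver, at 400 mg/L in drinking water for 16 weeks. In 3 mice a Cre recombinase driven from Lrat, a gene whose expression in liver marks hepatic stellate cells, was combined with a floxed Prmt1 allele (labelled Lrat-Cre; Prmt1f/f, called knockout mice here). The other 3 mice carried the floxed allele without Cre (labelled Prmt1f/f, called control mice here). Stellate cells are the main collagen-producing cells of the injured liver, and Prmt1 encodes the enzyme that makes most of the asymmetric dimethylarginine in cells. The comparison asked how the transcriptome of fibrotic liver differed between these genotypes. Every mouse had received TAA, so the effect of TAA itself was not measured. The labels give an age of 10 weeks beside 16 weeks of TAA and do not say to which time point the age refers, and they give no sex. The control mice (numbers 42, 83 and 90) had total counts of 14226832, 16462278 and 13303884. The knockout mice (49, 82 and 88) had 15479415, 14693392 and 14704540. Between 15168 and 15875 genes were detected per mouse. No pair of libraries agreed within sampling noise. The chi-square per degree of freedom over genes was lowest between knockout mice 82 and 88 (16.3) and next lowest between control mouse 42 and knockout mouse 49 (28.4).

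Prmt1 was measured first, as the gene that the genotype targets. Its level was 44.4 ± 5.44 CPM (scaled counts, SD, n = 3) in control livers and 28.8 ± 6.11 CPM (SD, n = 3) in knockout livers, 64.8% of the control level. The gene lies on chromosome 7 from 44975989 to 44986568 (minus strand, GENCODE annotation of GRCm38). All 3 knockout mice lay under all 3 control mice. The levels were 35.8 CPM in mouse 49, 24.7 in mouse 82 and 25.8 in mouse 88, against 38.9, 44.4 and 49.8 in control mice 42, 83 and 90. The log2 fold change was -0.62 (SE 0.20, 95% interval -1.08 to -0.17), with an adjusted p of 0.347 in edgeR's quasi-likelihood test over all genes. The adjusted p was 0.166 in DESeq2 and 0.352 in limma-voom. Only limma-voom with library weights, chosen after seeing the data, gave a value under 0.05 (0.0384). The two-sided exact permutation p was 0.1, the smallest that 20 assignments of 3 mice against 3 can give. Whole liver holds many cells that do not express Lrat, and their Prmt1 counts are part of these levels.

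Across the transcriptome, the 10 genes with the smallest p and separate groups were all lower in knockout livers, and 5 of them (Timp1, Loxl1, Lox, Col14a1 and Thbs1) are members of the matrix or matrix remodelling lists. Timp1, an inhibitor of matrix metalloproteinases, had 6.09 ± 0.974 CPM in control and 0.866 ± 0.0616 CPM in knockout livers (log2 fold change -2.80, SE 0.33). Loxl1, a cross-linker of elastin, had 29.2 ± 2.06 against 6.26 ± 2.08 CPM (-2.23, SE 0.27; SD, n = 3 throughout). The class I histocompatibility gene H2-Q1 had 48.7 ± 9.94 against 13.1 ± 2.65 CPM (-1.90, SE 0.23). That value is uncertain because its near-identical family members can share reads. These 3 genes had an adjusted p of 0.0978 (edgeR), the smallest of all, and so did not pass 0.05. The others of the 10 genes with the smallest p and separate groups were Lox, the collagen cross-linking enzyme (-3.06), Id1, a target of BMP signalling (-1.91), Col14a1 (-1.50), Thbs1 (-1.58), Igfbp7 (-2.04), Cxcl14 (-2.37) and Meox1, each with an adjusted p of 0.17 in edgeR. Meox1, a homeobox gene, had 78 counts in the 3 control livers together and 6 in the 3 knockout livers, a ratio of 13.3 with a 95% counting interval from 5.83 to 37.2. None of these 10 genes had overlapping groups, a criterion of the choice.

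The number of genes past adjusted p 0.05 was 0 of 13153 with edgeR's quasi-likelihood test and 0 with limma-voom, while DESeq2 called 238 (115 higher and 123 lower in knockout livers). With a weight per library, an alternative chosen after seeing the data, limma-voom called 560 (302 higher and 258 lower). At an unadjusted p under 0.05 edgeR gave 1448 genes (666 higher and 782 lower), against 657.7 expected by chance. In 2222 genes (16.9%) the 3 mice of one genotype all lay above the 3 of the other, against 10% by chance. Both expectations are averages that carry no spread for correlated genes. Other splits of the 6 mice into 3 and 3 gave 50 to 1098 genes at an unadjusted p under 0.05 in edgeR. Without knockout mouse 49 edgeR called 13 genes, 9 higher and 4 lower. Without control mouse 42, control mouse 83 and knockout mouse 82 the unadjusted count was 2519, 865 and 775. Libraries of control mouse 42 and knockout mouse 49 lay close together, and with their numbers against those over 80 as a term, a split the labels do not describe as a batch, edgeR called 6 genes, all lower. On simulated counts of the same 13153 genes and libraries the same test recovered 24.4% of genes changed 2-fold and 84.6% of those changed 4-fold. The Benjamini-Hochberg cut-off loosens as more genes pass, and the simulation made 118.6 calls per run against 0 in the real comparison. Genes were also simulated independently of each other. These shares therefore do not measure recovery in the real libraries. There Timp1 (-2.80), Loxl1 (-2.23) and Lox (-3.06), each fitted beyond 4-fold, did not pass.

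**Figure D1:**
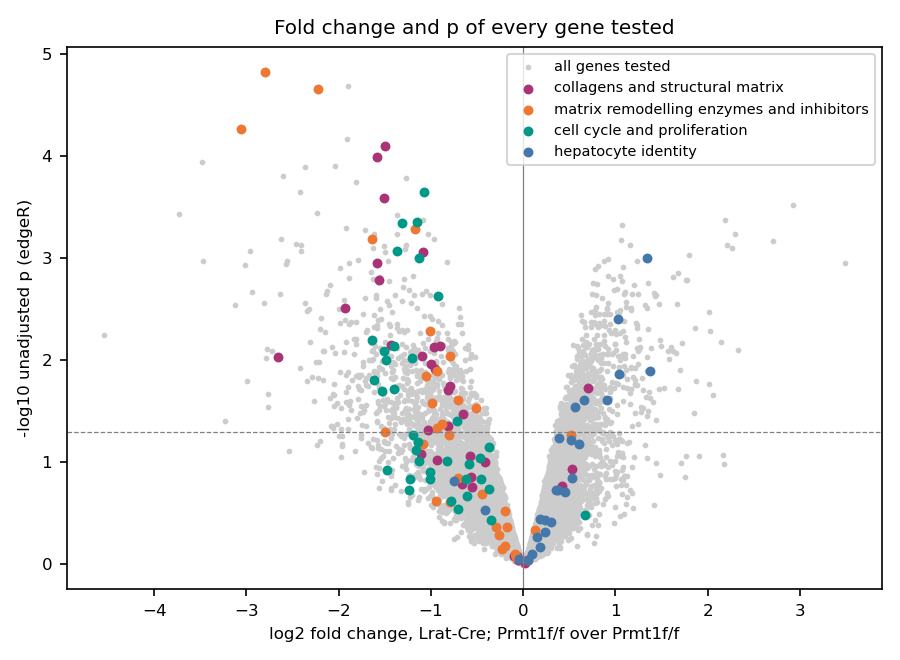
Each point is a gene tested, placed by its log2 fold change (knockout over control, x axis) and the negative log10 of its unadjusted edgeR p (y axis), with 4 gene lists in colour and unadjusted p 0.05 as a dashed line. Matrix, matrix remodelling and cell cycle genes lie mostly left of 0 and hepatocyte identity genes mostly right of it.

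Most collagen and matrix genes were lower in knockout livers. Of 35 genes tested, 29 had a negative fold change and the median log2 fold change was -0.81. When adjusted over the list alone 16 fell and 1 (Col18a1, 0.71, collagen of basement membranes) rose. Over all genes tested 0 passed with edgeR, while DESeq2 called 8, all lower. Col3a1, a fibrillar collagen, had 397.5 ± 98.0 CPM in control and 132.8 ± 57.0 CPM in knockout livers (log2 fold change -1.58, SE 0.33). Col1a1 had 238 ± 63.2 against 111 ± 42.3 CPM (-1.10, SE 0.33) and Col14a1 had 109.7 ± 11.4 against 38.8 ± 9.29 CPM (-1.50, SE 0.22). Col1a2 had a smaller difference, 220.9 ± 52.1 against 125.9 ± 53.8 CPM (-0.81, SE 0.35), and its log2 fold change was -0.50 without mouse 49. The list fell as a whole by camera with a preset correlation (adjusted p = 5.29e-09), with an adjusted p = 0.485 with an estimated correlation. Matrix remodelling enzymes and inhibitors also fell (32 genes, median -0.80, 29 negative, adjusted p = 3.51e-09; adjusted p = 0.466 with an estimated correlation). Of its members 7 were lower when adjusted over the list alone, among them Timp1, Loxl1 and Lox. Over all genes tested 0 passed with edgeR, and DESeq2 called 6, all lower. All 3 knockout mice lay under all 3 control mice in the mean of both lists, mouse 49 lowest at -1.34 and -1.07 log2 from the control mean. Without mouse 49 the shift of the matrix list mean was -0.51, against -0.79 with all mice.

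**Figure D2:**
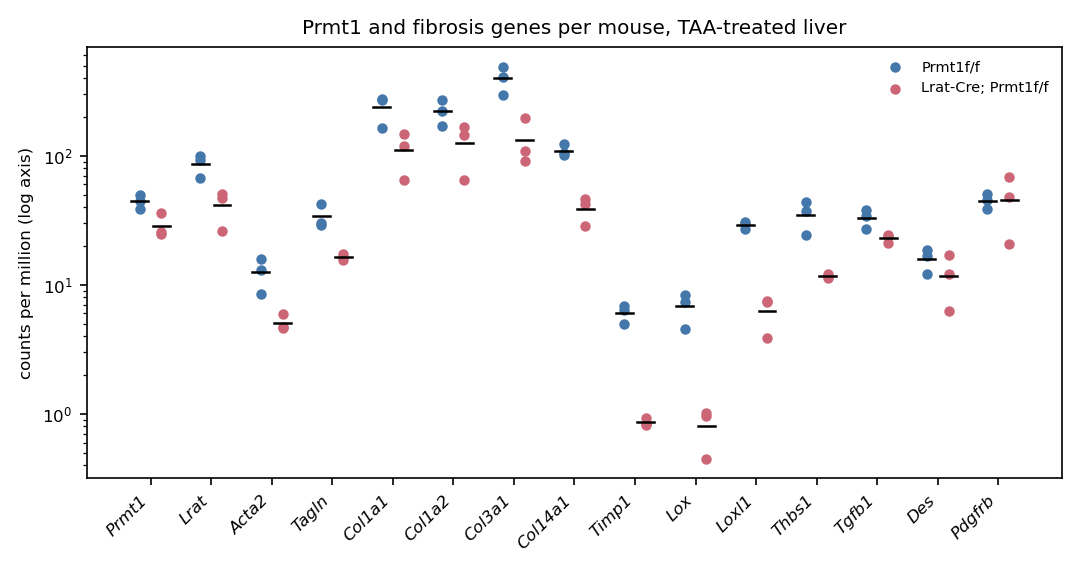
CPM on a log axis of Prmt1 and 14 genes of stellate cells and fibrosis in each mouse, with the mean of each genotype as a bar. Knockout mice lie at 0.837, 0.824 and 0.937 CPM in Timp1, all under the control mice, while the groups overlap in Des and Pdgfrb.

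Among stellate cell genes, those of the contractile, activated state and those of the quiescent state were both lower on average. Groups overlapped in the mean of the activation list. Acta2, which encodes the smooth muscle actin of activated stellate cells, had 12.5 ± 3.77 CPM in control and 5.09 ± 0.712 CPM in knockout livers (log2 fold change -1.29, SE 0.29). Tagln, a smooth muscle actin-binding protein, had 33.9 ± 7.21 against 16.5 ± 0.835 CPM (-1.04, SE 0.20). The activation list fell (24 genes, median -0.46, adjusted p = 3.59e-04 by camera; adjusted p = 0.567 with an estimated correlation). When adjusted over the list alone 7 were lower and 1 higher (Il1r1, the interleukin 1 receptor, 0.74). Over all genes edgeR called 0, and DESeq2 4 lower and 1 higher. The activation list mean shifted by -0.504 (SE 0.354), and control mouse 42 (-0.53) lay under knockout mice 82 (-0.404) and 88 (-0.159). Without knockout mouse 49 the list's adjusted p was 0.0609 and its median -0.25, and without mice 42, 83 and 88 the median was -0.76, -0.29 and -0.71. Lrat, which esterifies retinol for storage, had 86.6 ± 17.1 against 41.2 ± 13.2 CPM (-1.07, SE 0.27). Reln, a secreted glycoprotein of stellate cells, had 79.7 ± 24.0 against 39.7 ± 2.66 CPM (-1.01, SE 0.24). The quiescent identity list fell (20 genes, median -0.58, adjusted p = 3.37e-05; adjusted p = 0.466 with an estimated correlation). Vipr1 (-0.83), Reln, Rgs5 (-0.88) and Lrat were lower when adjusted over the list alone, and the list median was -0.34 without mouse 49. Des (-0.43, SE 0.35) and Pdgfrb (0.03, SE 0.36), which mark stellate cells and pericytes, overlapped between genotypes, Des being at -0.12 without mouse 49 and -0.81 without mouse 88. The sign of Pdgfrb was negative with limma-voom, with total counts as the only scaling and without the 20 most abundant genes. The TGF-beta list fell (27 genes, median -0.40, adjusted p = 4.18e-04; adjusted p = 0.485 with an estimated correlation), with 0 members past either adjustment with edgeR and a median of -0.17 without mouse 83. DESeq2 called Ltbp2 over all genes (adjusted p = 0.0461). The shift of its mean was -0.44 with all mice and -0.29 without mouse 49. Tgfb1 had 33.0 ± 5.55 against 23.2 ± 1.81 CPM (-0.51, SE 0.18) and Ltbp2, a binding protein of the latent-TGF-beta family, 44.9 ± 18.7 against 14.8 ± 8.24 CPM (-1.60, SE 0.48).

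Genes of the inflammatory infiltrate were lower in knockout livers on average, with wide spread among control mice. The cytokine and chemokine list fell (28 genes, median -0.61, adjusted p = 1.51e-05; adjusted p = 0.485 with an estimated correlation). Cxcl14 (-2.37), Ltb (-1.79), Ccl2 (-2.12) and Il1rn (-1.31) were lower when adjusted over the list alone. Neutrophil genes fell (7 genes, median -1.64, adjusted p = 9.56e-05; adjusted p = 0.466 with an estimated correlation). Csf3r (-1.01), S100a9 (-2.17), Cxcr2 (-1.64), S100a8 (-2.42) and Il1r2 (-2.17) were lower when adjusted over the list alone. The list of MHC class II and dendritic cell genes fell (14 genes, median -1.61, adjusted p = 5.73e-05; adjusted p = 0.485 with an estimated correlation). Ccr7 (-1.59) and Flt3 (-1.63) had its smallest p. Lymphocyte genes fell (18 genes, median -0.69, adjusted p = 0.00231; adjusted p = 0.567 with an estimated correlation). The macrophage list (29 genes, median -0.77, adjusted p = 0.0249; adjusted p = 0.649 with an estimated correlation) held Itgax (-0.96) and the scavenger receptor Cd163 (2.01) with opposite signs. The interferon-stimulated list (31 genes, median -0.40, adjusted p = 0.0211; adjusted p = 0.657 with an estimated correlation) included Igtp, at 105 ± 149 CPM in control and 26.8 ± 5.95 CPM in knockout livers. The control mean of Igtp rests on mouse 90, with 277.1 CPM against 16.7 and 21.4 in control mice 42 and 83. Its log2 fold change was 0.44 without mouse 90. In the cytokine, macrophage, lymphocyte, neutrophil, MHC class II and interferon lists control mouse 90 was the highest of the 6 mice, with list means of 1.04 (MHC class II), 0.81 (interferon) and 0.61 (macrophages) log2 above the control mean. Without mouse 90 the median of the MHC class II list was -0.65, that of lymphocytes -0.22, that of macrophages -0.30 and that of interferon-stimulated genes 0.05, and S100a9 was at -1.39. The shift of the cytokine list mean was -0.69 with all mice and -0.45 without mouse 90. Without control mouse 42 medians lay further from 0, at -1.05 (cytokines), -1.25 (lymphocytes), -2.51 (neutrophils) and -0.66 (interferon). Without mouse 88 the cytokine and lymphocyte medians were -0.92 and -1.14, and the interferon median was -0.24 without mouse 49 and -0.79 without mouse 82. Cd163 was at 3.08 without mouse 42 and 1.27 without mouse 82. Without mouse 90 the adjusted p was 0.992 for macrophages and 0.392 for interferon-stimulated genes, both with the direction of camera, which compares a list with the other genes, turned, and 0.756 for lymphocytes. The macrophage value was 0.11, 0.277 and 0.0818 without mice 83, 49 and 88. The interferon value 0.436 and 0.177 without mice 49 and 88. Endothelial genes did not pass the list test (23 genes, median -0.07, adjusted p = 0.602), Plvap (-0.75) and Ptprb (0.48) having the smallest p. Plvap was at -0.46 without mouse 90 and Ptprb at 0.26 without mouse 82. Without mouse 82 the adjusted p of the endothelial list was 0.0469 in the lower direction. Bile duct genes fell (18 genes, median -0.75, adjusted p = 0.00134; adjusted p = 0.567 with an estimated correlation). Cldn4 (-1.60, and -0.86 without mouse 83) and Muc1 (-1.22) led it. The list had an adjusted p of 0.194 and a median of -0.36 without mouse 83, and 0.18 and -0.44 without mouse 49.

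Hepatocyte identity, zonation, bile acid, gluconeogenesis and fatty acid oxidation genes were higher in knockout livers as lists, on average. Cholesterol synthesis genes fell, and lipogenesis and xenobiotic genes did not pass with all 6 mice. All knockout mice lay above all control mice only in the pericentral and gluconeogenesis means. Groups overlapped in the identity, periportal, bile acid and fatty acid oxidation means. In fatty acid oxidation knockout mouse 88 (-0.224) was the lowest of the 6 mice and knockout mouse 49 (0.769) the highest. Hepatocyte identity genes rose (25 genes, 22 positive, median 0.38, adjusted p = 3.05e-06; adjusted p = 0.485 with an estimated correlation). Nr1i3, the nuclear receptor CAR, had 5.16 ± 1.14 against 13.2 ± 2.92 CPM (log2 fold change 1.34, SE 0.28). Tdo2, a tryptophan-degrading enzyme, had 829 ± 37.0 against 1693 ± 435 CPM (1.03, SE 0.27). Both were higher when adjusted over the list alone. Pericentral genes rose (21 genes, median 0.43, adjusted p = 5.73e-05; adjusted p = 0.466 with an estimated correlation). Cyp2c37 (2.01), Fmo5 (1.11), Oat (1.57, and 1.03 without mouse 88) and Znrf3 (0.58) were higher when adjusted over the list alone. Without control mouse 83 the medians of the identity and pericentral lists were 0.21 and 0.24, and without control mouse 42 the pericentral median was 0.67. Periportal genes rose as well (20 genes, median 0.48, adjusted p = 2.54e-05; adjusted p = 0.485 with an estimated correlation). Hal (1.02) and Gls2 (1.11), both of amino acid breakdown, had the smallest p. Bile acid genes rose (19 genes, median 0.43, adjusted p = 7.23e-05; adjusted p = 0.466 with an estimated correlation). Of them 6 were higher when adjusted over the list alone, including the transporter Slco1a4 (0.99) and the FGF co-receptor Klb (0.91), and Cyp8b1, the sterol 12-alpha-hydroxylase, was lower (-1.92, and -2.88 without mouse 49). The shift of the bile acid mean was 0.38 with all mice and 0.18 without mouse 83, and the median was 0.65 without mouse 42. Genes of gluconeogenesis and fasting rose (18 genes, median 0.41, adjusted p = 0.00109; adjusted p = 0.466 with an estimated correlation). Igfbp2 (1.78) was higher when adjusted over the list alone, and the median was 0.25 without mouse 88. Pck1, which makes phosphoenolpyruvate, had 1616 ± 348 against 3486 ± 1108 CPM (1.11, SE 0.33). Genes of fatty acid oxidation rose (27 genes, median 0.29, adjusted p = 0.0108; adjusted p = 0.567 with an estimated correlation). Cyp4a14 was at 62.0 ± 20.97 against 472 ± 293 CPM (2.93, SE 0.51) and higher when adjusted over the list alone, and Ucp2, an uncoupling protein, was at -1.17. The list's adjusted p was 0.0673 without mouse 83 and 0.803 without mouse 49, with medians of 0.19 and 0.05. The shift of its mean was 0.24 with all mice, -0.02 without mouse 49 and 0.48 without mouse 88. Cyp4a14 and the other cytochrome genes named here belong to families whose members can share reads.

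Proliferation genes were lower in knockout livers, to differing degrees in the 3 mice. Of 36 cell cycle genes tested 35 had a negative fold change, with a median of -1.13. The list fell (adjusted p = 7.17e-17; adjusted p = 0.466 with an estimated correlation), and 12 genes were lower when adjusted over the list alone. Over all genes tested edgeR called 0 and DESeq2 called 8, all lower. The replication licensing genes Mcm6 (28.7 ± 3.73 against 13.7 ± 0.636 CPM, -1.07, SE 0.18) and Mcm3 (18.9 ± 3.32 against 8.51 ± 0.466 CPM, -1.15, SE 0.21) had the smallest p. The list mean was -0.33, -1.29 and -1.80 log2 from the control mean in mice 49, 82 and 88. Fetal and tumour-associated genes fell (13 genes, median -0.63, adjusted p = 0.00181; adjusted p = 0.485 with an estimated correlation). Ly6d (-1.61), Afp, the fetal albumin homologue (-0.96), and Akr1b8 (-0.97) were lower when adjusted over the list alone. The list had an adjusted p of 0.0749 and a median of -0.21 without mouse 83. Cholesterol synthesis genes fell (23 genes, median -0.59, adjusted p = 3.03e-04; adjusted p = 0.567 with an estimated correlation), with Insig1 at -0.51. Their mean was 0.31 above the control mean in mouse 49, and -0.93 and -1.19 in mice 82 and 88. Without mouse 42 the adjusted p was 0.0563, and the median was -1.32, -0.38 and -0.28 without mice 49, 82 and 88. Protein arginine methyltransferase genes, a list that includes Prmt1, fell (10 genes, median -0.18, adjusted p = 0.0314; adjusted p = 0.466 with an estimated correlation). Prmt2 had 8.34 ± 0.719 against 4.76 ± 0.637 CPM (-0.81, SE 0.24). The list had adjusted p values of 0.169, 0.0608 and 0.0986 without mice 42, 82 and 88, and a median of -0.36 without mouse 49.

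Of 35 lists tested, 26 passed camera with the preset correlation of 0.01 (18 lower and 8 higher), and 0 passed with an estimated correlation or with fry. Of these 26, 14 passed in each of the 6 fits that left out a mouse. The preset test treats genes of a list as nearly independent, and arbitrary regroupings of the same 6 mice gave up to 25 lists. Each regrouping still has most control mice on one side and most knockout mice on the other. Part of any genotype difference therefore stays in it.

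**Figure D3:**
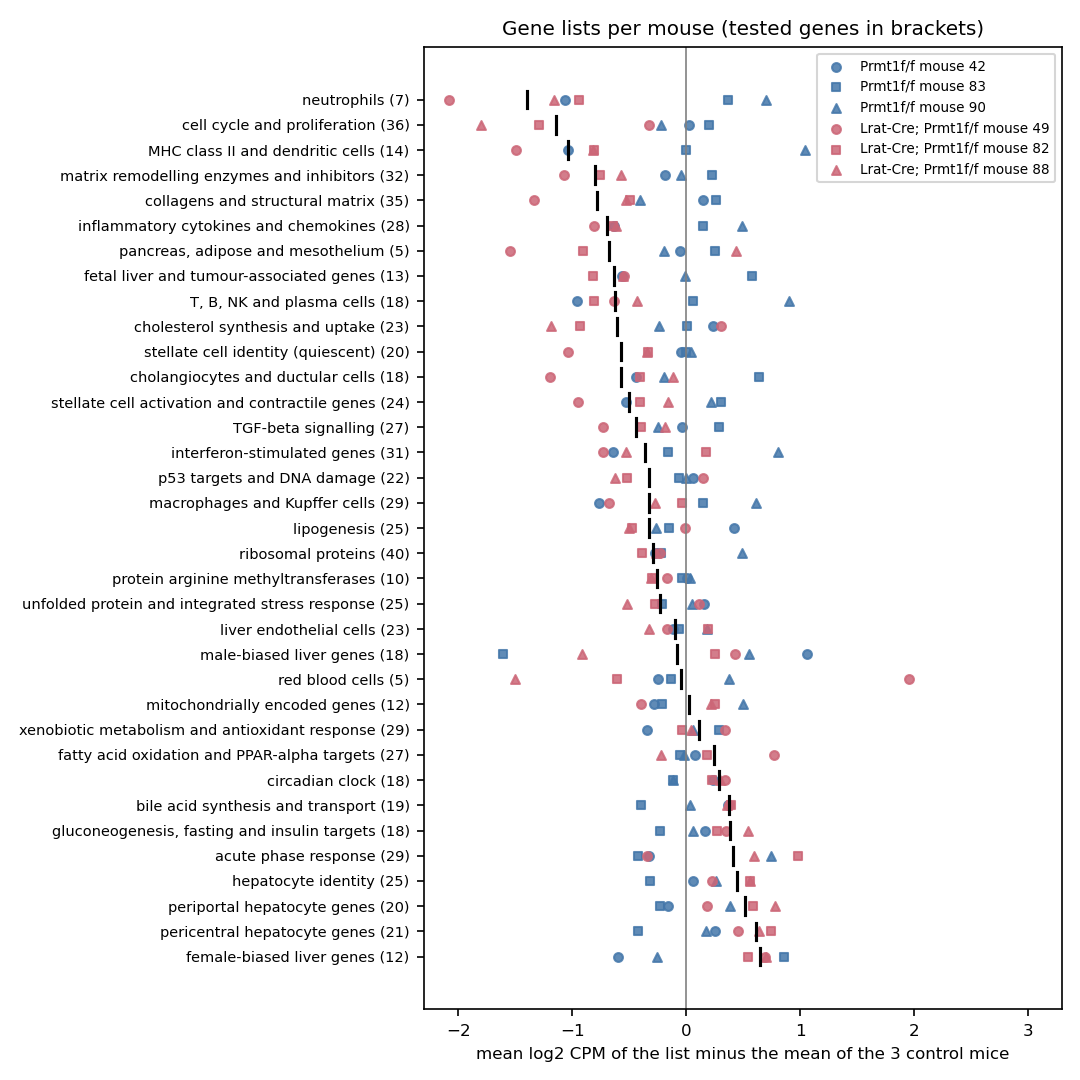
Mean log2 CPM of each gene list in each mouse, as the difference from the mean of the 3 control mice (x axis), with genotype as colour, mouse as symbol and the knockout mean as a black bar. In 5 lists all knockout mice lie under all control mice, in 2 above them, and in 28 the groups overlap.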

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

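The newer edgeR fit, limma-voom with library weights, the mouse number term and the mice numbered over 80 alone were chosen after seeing the data. The count of 0 genes past adjusted p 0.05 was the same with RLE size factors, total counts only, at least 1 CPM in 3 samples, limma-voom, the robust and newer edgeR fits, the 20 most abundant genes left out and the 4 mice numbered over 80. It was 4, all lower (Loxl1, H2-Q1, Timp1 and Id1) with no low-count filter, 3, all lower (Timp1, H2-Q1 and Loxl1) at adjusted p 0.10, 6, all lower, with the mouse number term, 238 with DESeq2 (115 higher, 123 lower) and 560 with library weights (302 higher, 258 lower); 212 genes were shared by the last 2, all in the same direction, and weights ran from 0.315 (mouse 90) to 2.98 (mouse 82). Leaving out a mouse gave 0 to 13 genes, 0 to 9 higher and 0 to 4 lower. Genes at unadjusted p under 0.05 numbered 775 to 2519 with a mouse left out, 2977 with weights and 2494 in mice over 80, and the cause was not tested. Prmt1 was lower in all alternatives, at -0.74 with an adjusted p of 0.0384 (limma) under library weights, the only alternative with a value under 0.05. List calls fell from 26 to 0 with an estimated correlation and to 0 with fry. Total counts only moved the median of all genes from -0.02 to -0.17. Signs of genes and directions of camera turned only where nothing had passed, apart from macrophage and interferon-stimulated genes. The mean of the fatty acid oxidation list, which had passed, was -0.02 without mouse 49, while that of macrophages stayed negative without mouse 90 (-0.022). Pdgfrb was -0.155 with total counts only, -0.127 with limma-voom, -0.001 without the 20 most abundant genes, -0.102 with the mouse number term and -0.421 to 0.379 with a mouse left out. Hba-a1 (1.42) was -0.134 with limma-voom, -1.316 with weights, -0.475 with the mouse number term, -2.476 in mice over 80 and -2.097 to 1.96 with a mouse left out. Slco1a1 (-1.57) was 0.507 with weights, 0.737 in mice over 80 and -2.123 to 1.049 with a mouse left out; Igtp was 0.063 with weights and -2.474 to 0.44, Smad6 -0.528 to 0.032 and Smad9 -0.421 to 1.297 with a mouse left out. For lists that turned, adjusted p with a mouse left out ran from 1.43e-05 to 0.436 (interferon-stimulated genes), 0.00435 to 0.975 (lipogenesis), 0.0469 to 0.887 (endothelial), 3.47e-06 to 0.992 (macrophages), 2.64e-05 to 0.498 (male-biased), 0.00948 to 0.859 (mitochondrial), 0.0389 to 0.996 (red blood cells) and 0.0257 to 0.949 (unfolded protein response). The male-biased list turned with total counts only (0.616), no low-count filter (0.833) and in mice over 80 (0.54), where red blood cells (0.0449) and xenobiotic genes (0.482) turned too. The cause was not tested. At this depth a gene such as Meox1 rests on 2 counts per knockout library.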

Other observations

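The tests of non-hepatocyte RNA, stellate cell share, dividing matrix cells, mouse 90 and BMP targets were chosen after the result was seen. Those of GC content and length, mouse 49 and the other splits were chosen before it. For non-hepatocyte RNA and dividing matrix cells, the condition for calling the test decisive was also made stricter after its value was seen. Circadian clock genes rose in knockout livers (18 genes, median 0.45, camera adjusted p = 4.09e-04; adjusted p = 0.466 with an estimated correlation). Ciart (0.76) and Cry2 (0.53) had the smallest p, Cry2 being at 0.35 and the list median 0.30 without mouse 90, and the labels give no time of collection. Acute phase genes rose as a list (29 genes, median 0.41, adjusted p = 0.00109; adjusted p = 0.567 with an estimated correlation). Lbp (1.18), which binds lipopolysaccharide, was higher and Hamp (-2.63), the iron hormone hepcidin, and Il1rn (-1.31) were lower when adjusted over the list alone. The list had an adjusted p of 0.0653 and 0.0549 without mice 42 and 82. Its median was 0.15, 0.69 and 0.71 without mice 82, 90 and 49, and its mean shift was 0.41 with all mice and 0.25 and 0.20 without mice 42 and 83. Ribosomal protein genes fell (40 genes, 39 negative, median -0.33, adjusted p = 3.13e-04; adjusted p = 0.567 with an estimated correlation), with 0.407 and a median of -0.06 without mouse 90. Rps23 (-0.83) and Rpl37 (-0.75) have processed copies that can take reads, and Rpl37 was at -0.40 without mouse 90. Genes of the p53 response fell (22 genes, median -0.25, adjusted p = 0.0346; adjusted p = 0.567 with an estimated correlation). Cdkn2b (-1.86) and Bax (-0.75) led, and the adjusted p was 0.169, 0.107, 0.193 and 0.49 without mice 42, 90, 82 and 88. The p53 median was -0.08, -0.39, -0.58, -0.08 and -0.03 without mice 42, 83, 49, 82 and 88, and Bax was at -0.40 without mouse 90.

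Other lists did not pass with all 6 mice, though each of the 8 below passed when some mouse was left out. Stress response genes had an adjusted p of 0.418 (25 genes, median -0.02), with the serine and asparagine synthesis genes Phgdh (-1.48) and Asns (-2.19) lower when adjusted over the list alone. The value was 0.0378 and 0.0257 without mice 83 and 49, with medians of -0.16 and -0.14. Female-biased genes had an adjusted p of 0.067 (12 genes, median 0.40), with Cyp3a41a (2.70) and Cyp3a44 (2.21) higher when adjusted over the list alone. The list passed in the higher direction without mouse 83 (5.49e-04) and mouse 82 (0.0266). Its median was 1.08 without mouse 83, -0.07 without mouse 42, -0.14 without mouse 88, 0.02 without mouse 90 and 0.10 without mouse 49. These are near-identical neighbours that can share reads. Male-biased genes had 0.811 (18 genes, median -0.39), Slco1a1 (-1.57) and Cyp2u1 (-0.95) having the smallest p. The value was 2.64e-05 and the median -0.83 without mouse 83, and the median was 0.15 and -0.09 without mice 42 and 88. Slco1a1 was at 1.05 without mouse 42. Per mouse the male-biased mean ran from -1.61 in control mouse 83 to 1.06 in control mouse 42. The Y-linked genes had counts in all 6 mice, with Ddx3y at 67.7 ± 8.05 CPM in control and 83.5 ± 2.30 CPM in knockout livers and Uty at 16.1 ± 3.65 and 21.2 ± 0.967 CPM (SD, n = 3). The lowest values, both in control mouse 90, were 59.7 CPM for Ddx3y and 12.4 CPM for Uty. These values argue against a female mouse among the 6, although the labels give no sex. Lipogenesis genes had an adjusted p of 0.067 (25 genes, median -0.42; Mlxipl 1.22, Pnpla3 -1.81). They passed in the lower direction without mice 83 (0.0201), 90 (0.00492) and 49 (0.00435), while the median was -0.04 without mouse 42, and Pnpla3 was at -2.84 without mouse 49. Xenobiotic genes had 0.158 (29 genes, median 0.09), led by the reductase Por (465 against 928 CPM) and Cyp3a25 (0.77). They passed in the higher direction without mice 83 (0.0378), 90 (0.0284) and 82 (0.0291). The shift of their mean was 0.11 with all mice and 0.00 without mouse 49, where the median was -0.09. Mitochondrially encoded genes had 0.733 (12 genes, median -0.08 with the test pointing up; mt-Nd4l 1.04, mt-Nd3 0.35). Their value was 0.00948 and the median 0.26 without mouse 90, and mt-Nd3 was at 0.12 without mouse 82. Red blood cell genes had 0.65 (5 genes, median 0.79, mean over mice -0.05; Hba-a1 1.42, Alas2 0.62). Without mouse 49 they passed in the lower direction (0.0389), with a median of -1.72 and Hba-a1 at -2.10. Alas2 was at 1.42 without mouse 42 and 0.20 without mouse 83. Pancreas, adipose and mesothelium genes had 0.251 (5 genes, median -0.31; Gpm6a -0.66, Msln -1.25). Without mouse 88 they passed in the lower direction (0.00333), with a median of -0.90 and Msln at -4.77. Without mouse 49 the median was 0.07, Gpm6a was at -0.33 and Msln at -0.69.

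Matrix and stellate cell lists were lower in the knockout livers on average, with overlapping groups in the activation list. A trend with transcript GC content and length is argued against, since the median of the matrix list was -0.81 before and -0.905 (SE 0.15) after its removal. That SE comes from resampling the genes of the list and does not measure the spread between mice. Over mice, the shift of the list mean had an SE of 0.344. Mouse 49 carries part of the size of the fall, the shift of the list mean being -0.787 with it and -0.512 without it. Mouse 49 does not carry all of it, since mice 82 and 88 (-0.493 and -0.532) also lay under every control mouse. That gap was narrow, with control mouse 90 at -0.408 and a control SD of 0.358. Without mouse 49 the adjusted p was 3.26e-04, by a preset camera that calls lists in arbitrary splits too. A smaller share of stellate cells may contribute: 18 identity genes without matrix genes differed by -0.552 (SE 0.217, log2), with all 3 knockout mice under all 3 control mice, and by -0.337 without mouse 49. Of the 20 genes tested in the full identity list 18 were lower, but Cxcl12 (0.02) and Ntm (0.22) were not. Pdgfrb, which also marks stellate cells, was at 0.03. A general loss of non-hepatocyte RNA stays open, because the endothelial minus matrix difference was 0.684 (SE 0.405), within 2 standard errors of 0 as such a loss predicts, while the same interval reaches a loss that spares endothelial genes. The endothelial mean alone differed by -0.102 (SE 0.18), a small difference whose spread over mice does not exclude a loss. Bile duct genes, also outside hepatocytes, differed by -0.571 (SE 0.459). Neutrophil, MHC class II, lymphocyte and macrophage means differed by -1.396 (SE 0.643), -1.042 (SE 0.643), -0.627 (SE 0.548) and -0.33 (SE 0.447). The hepatocyte identity mean differed by 0.45 (SE 0.203). Groups overlapped in each of these list means.

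The cell cycle list was lower in the knockout livers. GC content and length are argued against by a median of -1.073 (SE 0.106) after the correction, from -1.13 before it. This SE too comes from resampling genes, while the shift of the list mean had an SE of 0.449 over mice. Fewer dividing matrix-producing cells could account for it, but mouse 49, lowest in the matrix list, was the highest of the 3 knockout mice in the cell cycle list (-0.328), a value against this idea that rests on 1 mouse and lies under all control mice. The cause therefore stays open, and a direct effect of genotype on division was not tested.

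Immune cell and interferon lists were lower in the knockout livers on average. Control mouse 90 could be the source of part of this, since without mouse 90 alone 2 of the 5 lists, neutrophils (0.00602) and MHC class II (0.0368), still passed adjusted p 0.05 in the lower direction by camera. That was the preset camera, which calls lists in arbitrary splits too. Control mouse 42 lay among the knockout mice in both lists. Its neutrophil mean was -1.061, against -2.085, -0.942 and -1.16 in mice 49, 82 and 88. For MHC class II it was -1.04, against -1.495, -0.811 and -0.821. The shift of the MHC class II mean was -1.042 with mouse 90 and -0.52 without it. The part in macrophages, lymphocytes and interferon-stimulated genes cannot be told apart from the state of that single mouse.

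Id1, Id3 and Hamp, targets of BMP signalling, had log2 fold changes of -1.91, -0.97 and -2.63 with separate groups. Hamp had 811.9 ± 549.5 CPM in control and 130.7 ± 58.6 CPM in knockout livers (SD, n = 3). Its groups lay close, with 213.1 CPM in control mouse 83 and 191.5 CPM in knockout mouse 88. Lower activity of BMP signalling is a candidate explanation: the other targets Id2 (-0.57), Id4 (-0.65), Smad6 (-0.24), Smad7 (-0.55), Smad9 (0.41), Atoh8 (-0.39) and Bambi (-0.69) had a median of -0.554, although each of them but Id2 moved by over 1.5 times when some mouse was left out, with a camera p of 0.0109 in limma at the preset correlation and 0.171 with an estimated one. Smad6, Smad7 and Bambi are also in the TGF-beta list, whose result had been seen. Among BMP ligand genes, Bmp2 (0.28) was higher and Bmp4 (-0.25), Bmp5 (-0.71), Bmp6 (-0.23), Bmp10 (-0.35) and Gdf2 (-0.47) were lower. The smallest unadjusted edgeR p among these ligand genes was 0.0665 (Bmp5).

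The 10 splits of the 6 mice into 3 and 3 are too few for a share under 0.05. Of these, 1 split, the real one, gave as many genes at unadjusted p under 0.05 (1448; highest other 1098), 1 gave as many lists past adjusted p 0.05 (26; highest other 25) and 1 as large a shift of the matrix list mean (0.787; highest other 0.73). For genes past adjusted p 0.05 the real value was 0, so all 10 had to give at least as many and the comparison decides nothing. The highest other was 2. Every split but the real one still has most control mice on one side and most knockout mice on the other. Part of any genotype difference therefore stays in these splits. The split of control mouse 42 with knockout mice 49 and 82 against the rest gave the 1098 genes and the 25 lists. It keeps both mice numbered under 50 together. With that number as a term, the comparison of genotypes gave 6 genes in edgeR and 27 lists by camera. An effect of mouse number itself was not tested.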
